A study of Homo sapiens with 4 samples.

How the data were processed

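Gene expression was measured with 1 Affymetrix oligonucleotide array per sample in 4 human samples, cancer-associated fibroblasts (CAFs) and adjacent normal omental fibroblasts of 2 donors, called A and B here. The arrays were grouped by the cell type in the labels and paired by the donor in the labels, and replicate 1 of each group is donor A and replicate 2 donor B. The deposited values are one intensity per probe set on a linear scale, summarised with MAS5 per the submitters' processing notes. The MAS5 version, the scaling target and any filter are not given in the sources used here. The values themselves have a 2% trimmed mean of 500 on each array, as after global scaling to one target. Such scaling sets the arrays to a common average, so a change in total RNA per cell cannot be seen. MAS5 keeps low signals noisy, and detection calls were not used here. A log2 fold change near the floor is therefore pulled towards 0 by the pseudocount. All 4 deposited columns were used.

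Of the 54675 probe sets, 62 are controls. In the platform annotation supplied, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none, the latter being unnamed here rather than without a gene. Symbols were updated by gene ID through the RefSeq table of assembly GRCh38.p14, which 41037 probe sets matched, and no coordinates were taken from it. Probe sets with several symbols name no gene here. Each of the 19740 named genes was represented by its probe set of highest mean log2 value over the 4 arrays. Genes with a mean at or above the 50th percentile of all non-control probe sets, a mean log2(signal + 16) of 6.36, were tested, which left 12395. XIST and genes of the Y chromosome were left out of every table. Genes whose presence or sequence differs between people, such as classical HLA genes and GSTM1, were tested but are not printed. That exception was made after the values were seen, and the next gene by the rule took the place of 1 such gene. Of the 97 genes the rule named, 44 had several probe sets above the filter, in 1 direction for 42 and in both for 2 (KRT7 and FOLR1). Sizes could differ between probe sets of one direction, as for HK2 (0.02 to 1.11) and PECAM1 (0.07 to 2.02).

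Signals were tested as log2(signal + 16) in R 4.3.3 with limma 3.58.1, by lmFit and eBayes with an intensity trend, on all 4 arrays with terms for donor and group. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(signal + 16) scale, which understates the change of low genes. The donor term was used because the labels give both cell types of each donor. Across genes, the donor difference in normal fibroblasts and that in CAFs correlated at 0.249. With 2 pairs the fit has 1 residual degree of freedom, and limma added 3.62 prior degrees of freedom by sharing variance across genes. An exact permutation test of 2 pairs cannot give a two-sided p under 0.5, so none was used. The p-values rest on the spread between 2 donors and, by more degrees of freedom, on the variance shared across genes.

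The design, the alternatives, the rule for named genes and 21 gene lists (539 genes, 433 tested) were fixed before the data were examined. By the rule, the text names up to 10 genes per direction past the threshold with the same sign in both donors, filled up from genes with the same sign ranked by the smaller of the donors' absolute changes. It also names ACTA2, FAP, PDPN, S100A4 and CCL5, and up to 2 genes per direction from each list. The other genes named (CD14, CD163, PLAU, TOP2A, CDKN1A and COL1A2 in the report, and members of the second lists) were chosen after their values were seen. List members with no name in the annotation supplied were not analysed here. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated from the residuals and with fry, which tests whether the genes of a list move one way on balance. Camera with an estimated correlation has only the 1 residual degree of freedom of the fit, so it could hardly call any list. Its smallest unadjusted p over the 21 lists was 0.184, and its results here decide little either way. Of the 9 lists past the threshold with the preset correlation, 0 passed with an estimated one. Fry called 1 list, the matrix proteases (adjusted p 0.0222). In its form for changes in either direction fry called 6. Second lists of macrophage, T and B cell, interferon-gamma-inducible, epithelial, fibroblast identity and adventitial fibroblast genes were written after the first results were seen and before their own members were looked up.

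The test was checked on simulated data, 5 runs for CAF against adjacent normal over 12395 genes. Genes changed by 1, 2, 3 and 4 log2 units were recovered in 13.2%, 67.2%, 86.4% and 91.2% of cases, and 104 of 749 calls (13.9%) were false, above the 5% aimed at. Of unchanged genes, 5.7% had an unadjusted p under 0.05. Camera with the preset correlation recovered 2 of 2 shifted lists and called 0 others, and with an estimated correlation it recovered 0 of the 2. In the real data the estimated correlation was 1 for the cell cycle and leukocyte lists. With 1 residual degree of freedom, that value shows only that all members of a list differed between the donors in the same direction. The simulated genes varied independently. The check thus cannot show how often the preset correlation gives false calls for lists whose genes move together. Alternatives covered the pseudocount (1 and 64), the filter (none and the 75th percentile), quantile normalization, median centring, the mean over probe sets, every probe set by itself, no intensity trend, no donor block, each array left out in turn and a size of 3-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.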

Results

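Cancer-associated fibroblasts (CAFs), the fibroblasts of a tumour's stroma, and fibroblasts of adjacent normal omentum, the fatty fold of peritoneum, were profiled from each of 2 donors. Total RNA of each sample was hybridised to 1 whole-genome oligonucleotide array of 54675 probe sets, which gave 4 arrays, 2 per group. The donors are called A and B. The labels do not give the tumour type, how the fibroblasts were isolated or whether they were cultured. The series was laid out to set the CAFs of a donor against the adjacent normal fibroblasts of the same donor, and thus addresses which transcripts differ between them. The 4 arrays had median signals of 68.8 to 74.0, and 43.8% to 44.4% of probe sets reached a signal of 100. Across all probe sets, log2 signals of any pair of arrays correlated at 0.953 to 0.965 (Pearson, across probe sets, which are not independent replicates). The signal ratio of 3' to 5' control probe sets was 0.931 to 0.984 for GAPDH and 1.22 to 1.28 for ACTB. The number of arrays limits the precision of every value given here.

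ACTG2 and MMP9 rose in the CAFs of both donors, and PSG5, ABCA8 and PTGIS fell. ACTG2, the gamma actin of enteric smooth muscle, rose 22.7-fold, from a mean signal of 163 ± 124 to 4126 ± 3038 (SD, n = 2). MMP9, a secreted gelatinase, rose from 861 ± 412 to 8867 ± 4445. PSG5, a pregnancy-specific glycoprotein, was 17.8-fold lower in the CAFs, at 113 ± 41.2 against 2278 ± 729. ABCA8, a lipid transporter, was 12.5-fold lower, at 257 ± 204 against 3590 ± 3034, and PTGIS, the prostacyclin synthase, was 6.53-fold lower, at 2646 ± 427 against 17290 ± 1769. These 5 genes, 2 higher and 3 lower, were the ones past an adjusted p of 0.05 among the 12395 genes tested with limma with donor as a block. All 5 had an adjusted p of 0.0418 by limma, and each moved the same way in both donors. The log2 fold changes were 4.50 ± 0.19 (SE) for ACTG2, 3.33 ± 0.15 for MMP9, -4.16 ± 0.21 for PSG5, -3.64 ± 0.20 for ABCA8 and -2.71 ± 0.14 for PTGIS. ACTG2 had a log2 fold change of 4.56 in donor A and 4.45 in donor B, and PSG5 had -4.15 and -4.16. A second probe set of PSG5 above the filter had a log2 fold change of -0.28, while the 3 probe sets of PTGIS lay between -2.96 and -2.48. With the mean over all probe sets of a gene, including those below the filter, the log2 fold change was -1.08 for ABCA8, 2.22 for ACTG2 and -2.22 for PSG5, and these 3 no longer passed. Over all alternatives it ran from -4.63 to -1.08 for ABCA8, 2.22 to 5.33 for ACTG2, -4.49 to -2.22 for PSG5, 2.79 to 3.86 for MMP9 and -2.87 to -2.54 for PTGIS. An unadjusted p under 0.05 was reached by 1494 genes, 874 higher and 620 lower, where 620 would be reached by chance alone, and 149 genes had an adjusted p under 0.1. Without the donor block, limma called 0 genes (smallest adjusted p 0.077) and 1112 had an unadjusted p under 0.05. Leaving out any one of the 4 arrays, which also breaks the pairing, likewise left 0 genes, with 1660 genes at an unadjusted p under 0.05 without adjacent normal replicate 1, 1184 without adjacent normal replicate 2, 664 without CAF replicate 1 and 896 without CAF replicate 2.

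**Figure D1:**
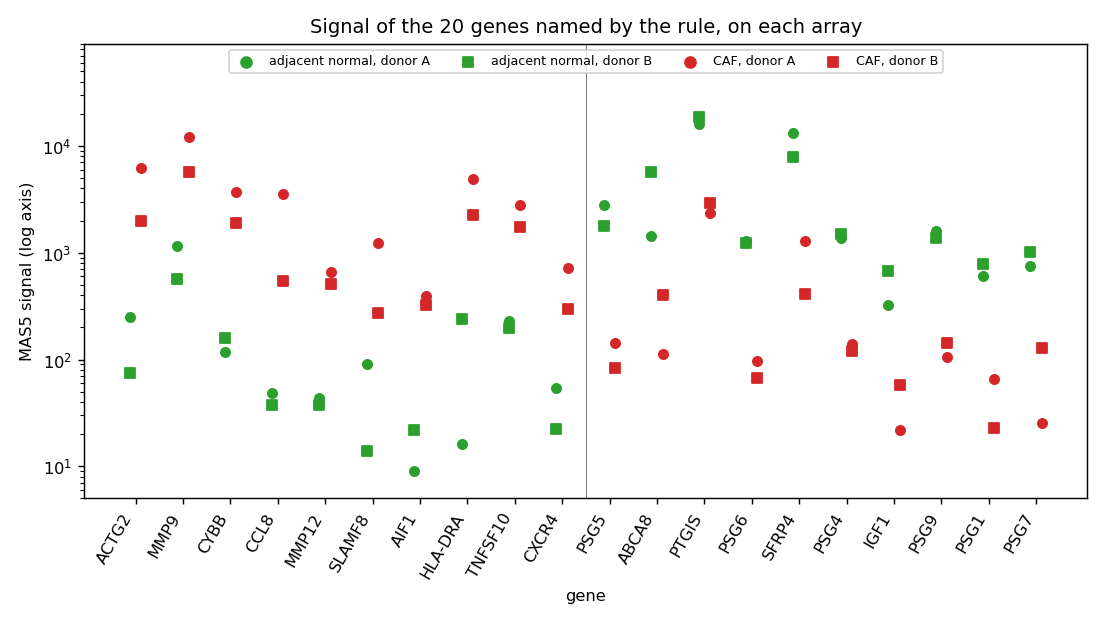
MAS5 signal (log axis) of the 20 genes ranked first by size and by the same direction in both donors, on each of the 4 arrays. Green marks adjacent normal fibroblasts, red marks CAFs, circles are donor A and squares donor B. The 10 genes left of the vertical line were higher in the CAFs of both donors and the 10 to its right lower, and 5 of the 20 (ACTG2, MMP9, PSG5, ABCA8 and PTGIS) passed the adjusted p of 0.05.

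Ranked by the smaller of the donors' changes, 8 more higher and 7 more lower genes had large log2 fold changes of the same sign in both donors, without passing the test over all genes. HLA-DRA, the alpha chain of an MHC class II molecule, had a log2 fold change of 5.22 ± 0.98 (7.27 in donor A, 3.16 in donor B), and CCL8, a monocyte chemoattractant, had 4.59 ± 0.61 (5.78 and 3.39). CYBB, the catalytic subunit of the phagocyte oxidase, had 4.13 ± 0.37, and AIF1, a macrophage actin-binding protein, had 3.60 ± 0.39. MMP12, the macrophage elastase, and SLAMF8 each had 3.41 ± 0.29, TNFSF10, which encodes the death ligand TRAIL, had 3.27 ± 0.22, and CXCR4, the receptor of CXCL12, had 3.19 ± 0.31. AIF1, CCL8, MMP12 and CXCR4 had signals under the filter's 66.1 in both normal samples, so that their sizes rest on the pseudocount. With pseudocounts of 1 and 64 in place of 16, the log2 fold change of AIF1 was 4.56 and 2.41, that of CCL8 4.99 and 3.79, that of MMP12 3.82 and 2.63 and that of CXCR4 3.67 and 2.38. On the same probe set, SLAMF8 had 3.98 and 2.59 and HLA-DRA had 5.71 and 4.45, but with a pseudocount of 1 another probe set of SLAMF8 became the brightest, with 2.48. The adjusted p of these 8 by limma ran from 0.0618 to 0.156. On the lower side stood 5 more pregnancy-specific glycoproteins, with log2 fold changes of -3.73 ± 0.25 for PSG6, -3.64 ± 0.43 for PSG1, -3.52 ± 0.41 for PSG7, -3.43 ± 0.26 for PSG9 and -3.31 ± 0.23 for PSG4. Of the 7 genes of this family tested, 7 were at least 2-fold lower in both donors, with a median log2 fold change of -3.52. All 10 probe sets of the family above the filter are of the kinds that can match several transcripts, so which of these near-identical genes the signal comes from is uncertain. SFRP4, a secreted Wnt antagonist, had -3.77 ± 0.25, from signals of 13110 and 7823 in the normal fibroblasts to 1278 and 414 in the CAFs, and IGF1, the insulin-like growth factor, had -3.19 ± 0.30 (-3.67 and -2.38 on the same probe set with pseudocounts of 1 and 64, and -2.52 on the probe set that is the brightest with 1). The adjusted p of these 7 lower genes ran from 0.0618 to 0.0899 by limma.

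The 2 donors shared a part of their changes. Among the 12395 tested genes, 419 were at least 2-fold apart in the same direction in both donors, 269 higher and 150 lower in CAFs. Taken alone, donor A had 598 genes at least 2-fold higher and 547 lower, and donor B had 821 higher and 337 lower. Independent lists of these sizes would share 39.6 higher and 14.9 lower genes. In opposite directions in the 2 donors, 39 genes were at least 2-fold apart, while 207 were at least 2-fold apart between donors in the same direction in both cell types. The donors' log2 fold changes had the same sign for 7262 genes (58.6%), and correlated across genes at 0.436 (Pearson) and 0.311 (Spearman), with no p given since genes are not independent replicates. Without the filter on low signals, the Pearson correlation was 0.277. COL10A1, a collagen of hypertrophic cartilage and tumour stroma, was among the shared genes, with a log2 fold change of 4.79 in donor A and 2.83 in donor B. Its normal signals, 39.3 and 36.5, lay under the filter's 66.1, so that its size rests on the pseudocount. EPCAM, an epithelial adhesion molecule, had 1.75 in donor A and 5.17 in donor B. Its normal signal in donor A, 8.90, lay under the filter, so that its size there rests on the pseudocount. At 3-fold or more in both donors stood 168 genes, 112 higher and 56 lower.

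**Figure D2:**
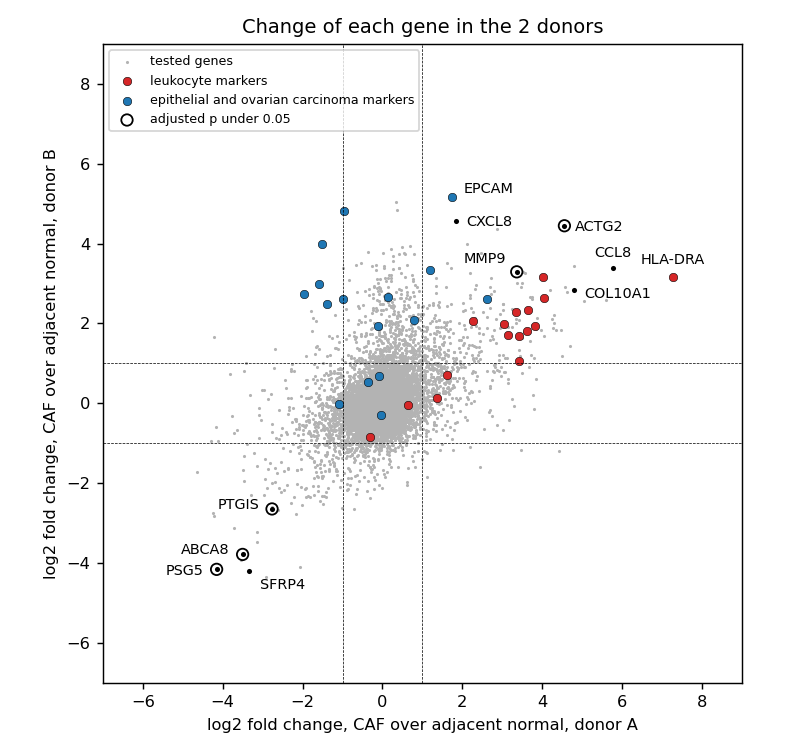
Log2 fold change (CAF over adjacent normal) of the tested genes in donor A (horizontal axis) and donor B (vertical axis), with dashed lines at 2-fold. Of the 12395 genes tested, those not printed, such as classical HLA genes, are not drawn. Red points are the leukocyte markers, of which 12 of 16 lie beyond 2-fold higher in both donors, blue points are the epithelial and ovarian carcinoma markers, 12 of 16 of which lie beyond 2-fold higher in donor B, and circles mark the 5 genes past an adjusted p of 0.05.

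The markers that usually define activated fibroblasts did not pass the test between the 2 cell types. ACTA2, the smooth muscle alpha actin, was among the brightest genes in both, at 19920 ± 1657 in normal fibroblasts and 23460 ± 4015 in CAFs (SD, n = 2), a log2 fold change of 0.23 ± 0.14 (SE). Its other probe set above the filter had 0.97, and the mean over its probe sets gave 0.47. The highest signals on the 4 arrays were 30306 to 36212, so a rise of ACTA2 from so bright a start may be understated. FAP, fibroblast activation protein, stood at 8747 ± 2402 and 8699 ± 1320, a log2 fold change of 0.01 ± 0.15, and PDPN, podoplanin, had 0.15 ± 0.18. S100A4, often called fibroblast-specific protein, had a log2 fold change of -1.62 in donor A and 0.15 in donor B, with a mean of -0.73 ± 0.44. The chemokine CCL5 had 1.42 ± 0.33, with 1.83 in donor A and 1.02 in donor B. The adjusted p by limma was 0.612 for ACTA2, 0.989 for FAP, 0.816 for PDPN, 0.602 for S100A4 and 0.222 for CCL5. As a group, the 21 CAF and myofibroblast markers had a median log2 fold change of 0.15 and did not pass camera, limma's test of a list against the other genes (adjusted p 0.299). That median was 0.04 without adjacent normal replicate 2 and 0.05 without CAF replicate 2. Of the 21, 0 passed limma over all genes, 3 had an unadjusted p under 0.05, and 1 was past the threshold adjusted over the list alone. That gene was PDGFRA, a receptor of platelet-derived growth factor, with a log2 fold change of -1.38 ± 0.16. CNN1, calponin, had 1.01, COL11A1, a fibrillar collagen, had 1.99 on average but 3.77 in donor A and 0.22 in donor B, and ASPN, a small matrix proteoglycan, had -0.74 on average but -1.41 in donor A and -0.07 in donor B, and 0.17 without adjacent normal replicate 1.

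Leukocyte markers rose as a group in the CAFs of both donors, and chemokines and interferon-stimulated genes rose with them. Of the 16 leukocyte markers tested, 12 were at least 2-fold higher in both donors, with a median log2 fold change of 3.38 in donor A and 1.87 in donor B. CD14, the monocyte lipopolysaccharide co-receptor, had a log2 fold change of 2.16 and CD163, a macrophage scavenger receptor, had 3.34, while the B cell gene CD79A had -0.58. The list passed camera with its preset correlation (adjusted p 6.26e-13), with adjusted p = 0.689 with an estimated correlation. Here and below, the latter test had 1 residual degree of freedom and could hardly call any list. For single members, 0 of 16 passed limma over all genes, 13 had an unadjusted p under 0.05 and 13 were past the threshold adjusted over the list alone, all 13 higher. The 31 chemokines and inflammatory cytokines, which recruit and activate leukocytes, had medians of 0.54 in donor A and 1.18 in donor B, with 10 at least 2-fold higher and 1 at least 2-fold lower in both. CCL8 is one of them, and CXCL8, a neutrophil chemoattractant, had 3.20 (1.83 in donor A, 4.58 in donor B), while IL33, an alarmin, had -2.00 and CCL11, an eosinophil chemoattractant, had -1.55 (-3.82 and 0.73). The chemokine list passed camera (adjusted p 6.8e-07), with adjusted p = 0.689 with an estimated correlation, and with 12 higher and 1 lower past the threshold adjusted over the list alone, against 0 over all genes and 18 at an unadjusted p under 0.05 by limma. Its call ended without CAF replicate 1 (adjusted p 0.103) and without adjacent normal replicate 2, where its median was -0.05 (adjusted p 0.538), against 1.58 without adjacent normal replicate 1. Over the alternatives tried, its adjusted p ran from 4.56e-11 to 0.538.

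Interferon-stimulated genes rose by less, with medians of 0.39 in donor A and 1.04 in donor B over 30 genes, 26 of them higher in both donors. CMPK2, a mitochondrial nucleotide kinase, had a log2 fold change of 1.51, RSAD2, the antiviral protein viperin, had 1.42, and IFIT2 had -0.07. The median over both donors, 0.74, was 0.34 without adjacent normal replicate 2 and 1.18 without adjacent normal replicate 1. None of the 30 was 2-fold higher in donor A and 15 were in donor B. The list passed camera (adjusted p 8.39e-13), with adjusted p = 0.689 with an estimated correlation. By limma 0 passed over all genes, 16 had an unadjusted p under 0.05 and 12 were past the threshold adjusted over the list alone, all higher. Matrix proteases and their inhibitors did not pass camera (27 genes, adjusted p 0.198), although MMP9 passed over all genes and 7 higher and 1 lower were past the threshold adjusted over the list alone. It passed as higher without CAF replicate 2 (adjusted p 0.0292, in a range of 0.0292 to 0.569 over the alternatives), and fry, which asks only whether its genes move one way, called it (adjusted p 0.0222). The list's mean was 0.46 and its median 0.23 in donor A and -0.07 in donor B. PLAU, the urokinase, had a log2 fold change of 1.80, while CTSK, cathepsin K, had -0.87, but 0.26 without adjacent normal replicate 1, and the inhibitor TIMP4 had -1.02. The medians of the leukocyte markers, 3.38 in donor A and 1.87 in donor B, and that of the epithelial markers in donor B, 2.61, stood beside each of these groups.

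**Figure D3:**
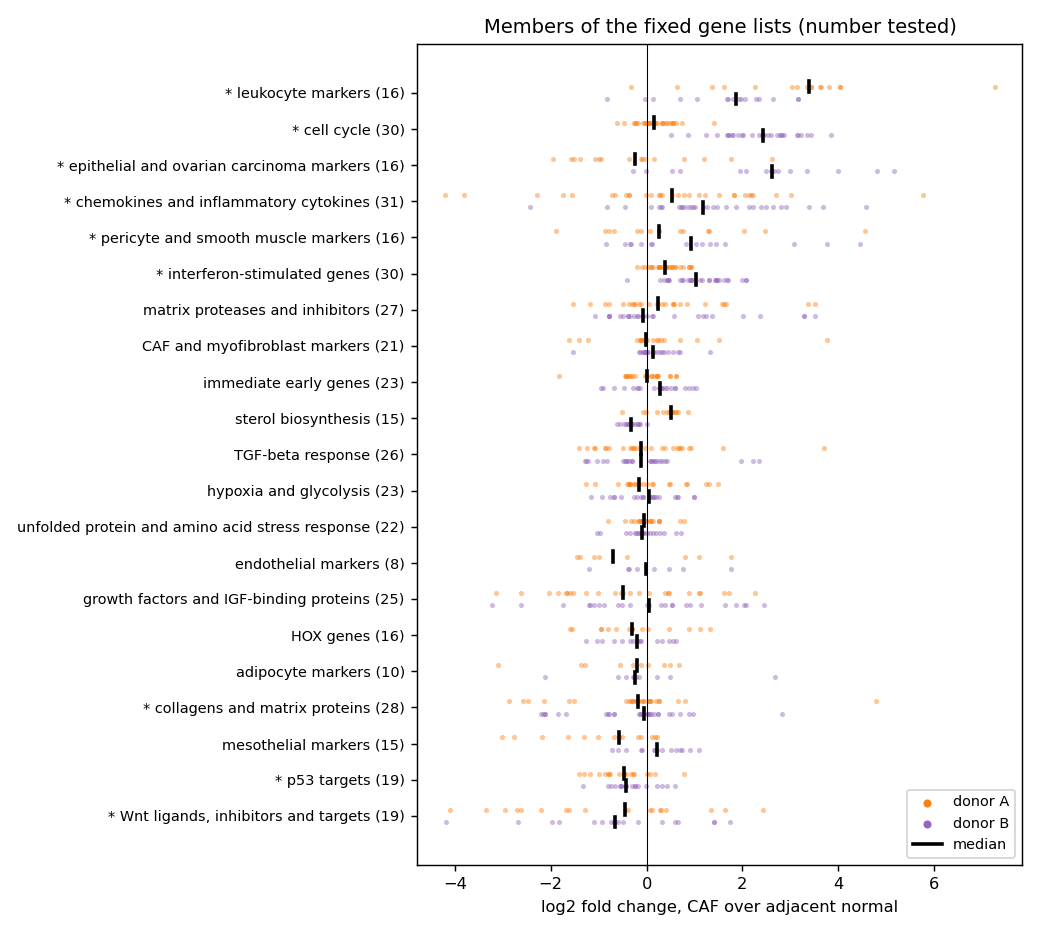
Log2 fold change (CAF over adjacent normal) of the members of the 21 fixed gene lists, with the number tested in brackets. Orange points are donor A, purple points donor B, and black bars are medians. An asterisk marks the 9 lists past camera's adjusted p of 0.05 with its preset correlation. None of them passed with an estimated correlation, where 1 residual degree of freedom hardly allows a call.

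Cell cycle genes rose in the CAFs as a list, with most of the difference in donor B, whose normal fibroblasts stood apart from the other 3 samples, while p53 targets fell. Of 30 cell cycle genes, 28 were at least 2-fold higher in donor B and 1 in donor A, with medians of 2.42 and 0.16. CDK1, the mitotic kinase, had log2 fold changes of 3.86 and 0.21 in donors B and A, and CCNE2, a G1/S cyclin, had 2.42 and 1.41. TOP2A, a topoisomerase of dividing cells, had signals of 2264 and 2865 in the CAFs of donors A and B, and 2148 and 313 in their normal fibroblasts, and CDK1 had 5077 and 6199 against 4374 and 413. The list's median over both donors, 1.29, was 0.29 without adjacent normal replicate 2 and 2.23 without adjacent normal replicate 1. The list passed camera (adjusted p 3.44e-11), with adjusted p = 0.689 with an estimated correlation, and by limma 0 of its members passed over all genes, 10 had an unadjusted p under 0.05 and 0 were past the threshold adjusted over the list alone. The difference between donors was not tested, since each donor has 1 array per cell type. The 19 p53 targets had medians of -0.47 in donor A and -0.43 in donor B, with 13 lower in both donors. SPATA18, a mitochondrial quality control gene, had a log2 fold change of -1.37, TP53INP1, a stress-response gene, had -0.88 and CDKN1A, the cyclin-dependent kinase inhibitor p21, had -0.76, while PLK2, a polo-like kinase, had 0.68. The p53 list passed camera (adjusted p 2.37e-05), with adjusted p = 0.689 with an estimated correlation. Leukocyte markers, with medians of 3.38 in donor A and 1.87 in donor B, and the epithelial markers of donor B, with 2.61, were higher beside both groups. By limma 8 lower and 1 higher p53 targets were past the threshold adjusted over the list alone, 0 passed over all genes and 10 had an unadjusted p under 0.05.

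Epithelial and ovarian carcinoma markers rose as a list, but moved apart in the 2 donors. In donor B, 12 of 16 were at least 2-fold higher in the CAFs and 0 lower (median 2.61), whereas in donor A 3 were at least 2-fold higher and 5 lower (median -0.24). EPCAM had a signal of 6236 in the CAFs against 157 in the normal fibroblasts of donor B, and of 67.8 against 8.90 in donor A. The difference between the donors was not tested. ST14, the epithelial protease matriptase, had a log2 fold change of 2.61 in donor A and 2.62 in donor B. Its normal signals were 15.0 and 73.8, so that the size in donor A rests on the pseudocount. KRT7, a simple epithelial keratin, had -0.54, with 1 of its 3 probe sets in the opposite direction. The list passed camera (adjusted p 0.0059), with adjusted p = 0.781 with an estimated correlation. By limma 1 was past the threshold adjusted over the list alone, 0 over all genes and 4 at an unadjusted p under 0.05. Without CAF replicate 2 the list's direction turned (median -0.39, adjusted p 0.0384, against a median of 2.63 without CAF replicate 1), and its call ended without adjacent normal replicate 1 (adjusted p 0.193) and without adjacent normal replicate 2 (adjusted p 0.054), and at the 75th percentile filter, which left 5 of its genes (median 0.30, adjusted p 0.74), in a range of 4.85e-18 to 0.74 over the alternatives.

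Collagens and matrix proteins fell as a list, with members on both sides. FBLN5, an elastic fibre protein, had a log2 fold change of -2.35 ± 0.20, OGN, osteoglycin, had -2.51 ± 0.35, and COL10A1 had 3.81 ± 0.53. The size for COL10A1 rests on the pseudocount, since both its normal signals lay under the filter's 66.1. COL8A1 had 0.57 ± 0.15, and the abundant fibrillar collagen gene COL1A2, named here after its values were seen, had -0.03 ± 0.16. The 28 collagens and matrix proteins had a median of -0.04 and a mean of -0.32, with 5 at least 2-fold lower and 1 at least 2-fold higher in both donors. They passed camera as lower (adjusted p 0.0354), with adjusted p = 0.689 with an estimated correlation. By limma 7 lower and 2 higher were past the threshold adjusted over the list alone, 0 passed over all genes and 11 had an unadjusted p under 0.05. The call ended in 6 of 13 alternatives: without adjacent normal replicate 1 (adjusted p 0.0898), without adjacent normal replicate 2 (0.0532), with quantile normalization (0.302, where the median was 0.03), at the 75th percentile filter (0.0805), with the mean over probe sets (0.0582) and with no intensity trend (0.0522). The adjusted p ran from 0.015 to 0.302 over the alternatives. The median was -0.06 without adjacent normal replicate 1, -0.13 without adjacent normal replicate 2, -0.12 without CAF replicate 2 and 0.03 without CAF replicate 1, where camera still called the list lower (adjusted p 0.0165). The leukocyte markers stood at medians of 3.38 and 1.87 in the same comparison.

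The list of Wnt ligands, inhibitors and targets fell in the CAFs, and that of pericyte and smooth muscle markers rose. Of the 19 Wnt genes, 4 were at least 2-fold lower and 2 at least 2-fold higher in both donors, with medians of -0.46 in donor A and -0.66 in donor B. SFRP4 and the ligand WNT2B (log2 fold change -2.65, with its 4 probe sets from -4.11 to -0.81) led the lower genes, and LEF1, a transcription factor of the pathway (1.92), and the ligand WNT5B (1.54) led the higher ones. The list passed camera (adjusted p 0.00583), with adjusted p = 0.689 with an estimated correlation, and by limma 7 lower and 3 higher were past the threshold adjusted over the list alone, with 0 over all genes and 13 at an unadjusted p under 0.05. The Wnt list's median over both donors, -0.88, was -0.32 without adjacent normal replicate 2, and its adjusted p ran from 0.000247 to 0.0498, the latter without adjacent normal replicate 1. The 16 pericyte and smooth muscle markers had medians of 0.26 in donor A and 0.93 in donor B, with 4 at least 2-fold higher in both. MYH11, the smooth muscle myosin, had a log2 fold change of 3.11 beside the 4.50 of ACTG2. The lowest of the list were RGS5, at -1.11 (-1.89 in donor A, -0.32 in donor B), and KCNJ8, at -0.85. Of the 16, 9 were higher and 4 lower in both donors. The size for MYH11 rests on the pseudocount, since its normal signals, 45.0 and 12.8, lay under the filter's 66.1. This list passed camera (adjusted p 0.00426), with adjusted p = 0.689 with an estimated correlation. By limma 6 higher and 1 lower were past the threshold adjusted over the list alone, and ACTG2 over all genes. Without adjacent normal replicate 2 its call ended (median 0.23 against 0.69, adjusted p 0.0883, in a range of 0.000264 to 0.0883 over the alternatives). Beside both lists, the leukocyte markers had medians of 3.38 in donor A and 1.87 in donor B, and the epithelial markers had 2.61 in donor B.

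Growth factor and TGF-beta genes went both ways, and neither list passed camera. Among 25 growth factors and IGF-binding proteins, IGF1 and PDGFD, a platelet-derived growth factor, were the lowest (log2 fold changes -3.19 and -2.19), and FGF1, a fibroblast growth factor, and GREM1, a BMP antagonist, the highest (1.71 and 1.67). By limma 8 lower and 5 higher were past the threshold adjusted over the list alone, 0 passed over all genes and 15 had an unadjusted p under 0.05. The list's median was 0.03, its mean -0.20 and camera's direction lower (adjusted p 0.368), but it passed as lower without adjacent normal replicate 2 (median -0.42, adjusted p 0.0165) and without CAF replicate 1 (median -0.34, adjusted p 0.0273), in a range of 0.0165 to 0.766 over the alternatives. Its median was 0.55 without adjacent normal replicate 1 and -0.13 without CAF replicate 2. Among 26 TGF-beta response genes, TGFB2, a ligand of the pathway, had 3.03 ± 0.38 and EDN1, endothelin, 1.79 ± 0.25. ID1, an inhibitor of differentiation, had -1.26 ± 0.14 and SMAD6, an inhibitory SMAD, -1.22 ± 0.23. By limma 5 lower and 3 higher were past the threshold adjusted over the list alone, 0 passed over all genes and 10 had an unadjusted p under 0.05. The TGF-beta list had a median of -0.07, a mean of 0.03 and a camera direction of lower (adjusted p 0.462). That median was 0.04 without CAF replicate 1 and -0.02 without adjacent normal replicate 2.

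Markers of mesothelial, fat and endothelial cells, which the omentum also holds, did not pass camera in either direction. The 15 mesothelial markers had medians of -0.58 in donor A and 0.22 in donor B (adjusted p 0.295). UPK3B, an uroplakin of mesothelium, had a log2 fold change of -1.75, SLPI, a protease inhibitor, had -1.35 (-3.02 in donor A, 0.33 in donor B) and TM4SF1 had 0.64. The 10 adipocyte markers had a median of -0.30 (adjusted p 0.271), with CFD, adipsin, at -1.75, PPARG, the regulator of fat cell formation, at -1.69 (-3.10 in donor A, -0.28 in donor B) and CD36, a fatty acid receptor, at 1.36 (0.04 in donor A, 2.69 in donor B). The adipocyte median was -0.16 without adjacent normal replicate 1. The 8 endothelial markers had a median of -0.22 (adjusted p 0.75), which was -0.58 without adjacent normal replicate 2 and -0.08 without adjacent normal replicate 1. PECAM1, which leukocytes also carry, had 1.76 in donor A and 1.76 in donor B, with its 3 probe sets from 0.07 to 2.02, beside KDR, a VEGF receptor, at -0.90. For the mesothelial list limma called 0 genes over all genes, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. The adipocyte and endothelial lists had 0 each over all genes, and 1 each both at an unadjusted p under 0.05 and adjusted over the list alone. The mesothelial list passed camera as lower without CAF replicate 2 (adjusted p 0.000351) and without adjacent normal replicate 2 (adjusted p 0.0432), in a range of 0.000351 to 0.86 over the alternatives.

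The lists of metabolic, stress and positional genes did not pass camera with the settings fixed in advance. Of 23 hypoxia and glycolysis genes, the glucose transporter SLC2A1 (log2 fold change 1.15) and the hexokinase HK2 (1.11, with its 3 probe sets from 0.02 to 1.11) were past the threshold adjusted over the list alone, while ADM, adrenomedullin, had -0.76 (-1.26 in donor A, -0.27 in donor B). The hypoxia list had a median of -0.10, a mean of 0.01 and a camera direction of lower (adjusted p 0.593). That median was -0.02 without adjacent normal replicate 1 and -0.05 without CAF replicate 1. The 15 sterol biosynthesis genes had medians of 0.50 in donor A and -0.31 in donor B (adjusted p 0.953), and LSS, the lanosterol synthase, had -0.53. The 23 immediate early genes had a median of 0.18 (adjusted p 0.365), with the transcription factors KLF6 at 0.65 and KLF4 at -1.15. Without CAF replicate 2 the immediate early median was 0.03. The 22 genes of the unfolded protein and amino acid stress response had a median of -0.00 (adjusted p 0.593), with DDIT3, a stress transcription factor, at -0.92 and SLC7A5, an amino acid transporter, at 0.53. With 1 array left out, this list's median ran from -0.21 (adjacent normal replicate 1) to 0.15 (CAF replicate 1). The 16 HOX genes, which mark position along the body axis, had a median of -0.17 (adjusted p 0.09), with HOXD8 at 0.96 and HOXB8 at -1.06, and 1, HOXC6 (-0.99), past the threshold adjusted over the list alone. With the mean over probe sets the HOX list passed as lower (median -0.42, adjusted p 0.0358, in a range of 0.0358 to 0.624 over the alternatives). Of these 5 lists limma called 0 genes over all genes, and 8, 1, 2, 2 and 4 genes, in the order given, had an unadjusted p under 0.05. Adjusted over the list alone, 0 passed in the sterol, immediate early and unfolded protein lists. Without adjacent normal replicate 1 the sterol list passed as lower (median -0.35, adjusted p 0.0005) and without adjacent normal replicate 2 as higher (median 0.41, adjusted p 8.86e-05), in a range of 8.86e-05 to 0.98 over the alternatives.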

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

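The counts from each donor alone were added after the data were seen, and all other alternatives were planned. The count of 5 genes past the threshold depended on the processing. It was 12 with a pseudocount of 1 and 12 with 64, 42 (16 higher, 26 lower) at the 75th percentile filter, 39 (20 higher, 19 lower, against 2 and 3) with median centring, and 57 with every probe set tested, and each of these held the same 5 genes. It was 0 with no filter, with quantile normalization, with no intensity trend and with no replicate block, where 1858, 1479, 1422 and 1112 genes had an unadjusted p under 0.05 by limma. Leaving out 1 array at a time gave 0 to 0 genes. In these fits the lone array of a group is assumed to vary like the other group. Averaging probe sets gave 6 genes, 2 of them shared. All 5 genes kept their direction in the 14 alternatives, passing in 5 or 6 each, with adjusted p of 0.0179 to 0.691, but not their size: ABCA8 ran from -4.63 to -1.08 and ACTG2 from 2.22 to 5.33. The filters change how many genes are adjusted for, and for the others the cause was not tested. The 419 genes at least 2-fold apart in both donors became 168 at 3-fold, 670 with no filter, 157 (80 higher, 77 lower, against 269 and 150) at the 75th percentile and 637 over every probe set, and were 282 to 461 otherwise. Without one donor no agreement can be counted, and 1145 genes in donor A alone and 1158 in donor B alone were 2-fold apart. The correlation of the donors' changes across genes was 0.277 with no filter and 0.40 to 0.438 otherwise. The 9 lists past camera were 0 with an estimated correlation and 1 with fry, 6 to 9 with the settings that kept all arrays, 9 with no replicate block, and 8 to 11 without 1 array at a time. Leukocyte, interferon, cell cycle, p53 and Wnt lists passed in all 13 alternatives of camera's settings with the preset correlation. Of 269 recomputed list medians, 21 in 9 lists had the opposite sign, among them collagens (0.029 with quantile normalization) and mesothelial markers (0.285 without CAF replicate 1). Camera's direction turned, with a call lost or gained, in 3 cases, whose cause was not tested: the chemokine list without adjacent normal replicate 2 (median -0.0535, in a range to 1.58 without 1 array), the epithelial list without CAF replicate 2 (-0.388, in a range to 2.63) and the sterol list without adjacent normal replicate 1 (-0.348, in a range to 0.41). Of 1314 recomputed values of named genes 1231 stayed on their side of the threshold, 43 lost and 40 gained a call, and 0 calls turned. Uncalled genes changed sign in 20 values of 17 genes, 0 of them under another scaling or pseudocount. Of those named in the report, FAP, PDPN, S100A4, ASPN, CTSK, CCL11, ADM, IFIT2, CD36 and KRT7 did so without 1 array, and PDPN, CD79A and FOLR1 with the mean over probe sets. With no filter 19740 genes entered, 12395 with the filter used and 7922 at the 75th percentile, and why the correlation was lower with no filter was not tested.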

Other observations

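The second lists were written after the first results were seen, and the tests of array scaling, of donor A alone for macrophage genes, of mesothelial genes and of shares without the filter were chosen only after the results were seen. Genes that interferon gamma induces in fibroblasts had medians of 0.51 in donor A and 0.72 in donor B over 18 genes. CD274, which encodes the checkpoint ligand PD-L1, had the largest value, a log2 fold change of 2.14 (2.33 in donor A, 1.95 in donor B, adjusted p 0.0881 by limma). The immunoproteasome subunit PSMB9 had 1.02, the peptide transporter TAP1 1.11 and the adhesion molecule ICAM1 1.15, while GBP2 had 0.06. Of 12 adventitial fibroblast genes tested, 3 were at least 2-fold lower in both donors: DPT, dermatopontin (-1.64), GPC3, a glypican (-2.17), and CD248, endosialin (-1.42). DPP4, a surface peptidase, had -2.35 in donor A and -0.17 in donor B. None of these genes passed the threshold over all genes.

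Leukocyte markers were higher in the CAFs of both donors. Array scaling alone is argued against, since a scaling moves genes of like signal alike. The 100 unlisted genes nearest in mean signal to each marker had a median of -0.0261 in donor A and 0.0179 in donor B. The markers lay above them by a median of 3.41 log2 units in donor A and 1.87 in donor B. On arrays scaled to a common average, values near 0 were likely beforehand. The comparison therefore adds little to the leukocyte medians of 3.38 and 1.87. For interferon gamma acting on fibroblasts as the whole cause, its list's median was at most 0.385 times the leukocyte median, under the bound set against it. Some genes of its list started bright in the normal fibroblasts of donor A, such as GBP1 (3818) and TAP1 (2503), while the leukocyte marker AIF1 started at 9.07. Changes from such unlike starts compare poorly, so the ratio argues against interferon gamma only weakly. Cells of the macrophage lineage are a candidate source in donor A, where 81.8% of 22 further macrophage genes were at least 2-fold higher. The filter keeps a gene silent in normal fibroblasts only if the CAFs raise it, which favours a high share, and without the filter the share was 77.8% of 27. Among the genes were C1QC at 1354 against 46.2 and MRC1 at 1143 against 43.5. For both donors together the share was 50%, and 44.4% without the filter, between the bounds set for and against. In donor B, C1QC stood at 507 against 130. In neither donor can such a share tell macrophage cells from fibroblasts that express such genes, since each array holds the RNA of a whole sample. GPNMB and LGMN, bright in the normal fibroblasts too, were not 2-fold higher in either donor. Nor were CD4 and MS4A6A, which were dim there (110 and 76.2 in donor A). Only 1 gene of the T and B cell list was tested (CD6, log2 fold change 0.91). Without the filter, which most genes of that list failed, 5 of 13 (38.5%) were at least 2-fold higher in donor A and 2 (15.4%) in donor B. At such low signals MAS5 values are noisy, so these shares say little about T and B cells. The labels name no sort or gate.

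Epithelial markers were higher in the CAFs of donor B. More mesothelial cells than in the normal sample are argued against as the source, since the mesothelial list had a median of 0.221 there. That median was already known when its bound was chosen. It does not bear on mesothelial cells present in both samples alike. Epithelial cells in the CAF sample of donor B may account for the higher markers, since 73.3% of 15 further epithelial genes were at least 2-fold higher in donor B. Without the filter the share was 60.9% of 23, just above the 60% set in advance. Among them were EHF (2322 against 54.9) and DSP (8837 against 2891). DSP was also higher in donor A (5807 against 839), where 1 of the 15 genes was at least 2-fold higher and 3 lower. An epithelial programme within the CAFs themselves stays open, as untested.

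Some matrix and secreted genes, among them FBLN5, OGN and the Wnt antagonist SFRP4, were lower in both CAF samples, although the 28 collagens and matrix proteins had a median of -0.04 and 5 of them were at least 2-fold lower in both donors. Dilution of fibroblast RNA by other cells is argued against as the whole cause, since 22 fibroblast identity genes had medians of -0.158 in donor A and -0.231 in donor B. Only LRRC17 of the 22 was at least 2-fold lower in both donors (log2 fold change -2.28). A different fibroblast state, or a different site of origin, might account for it, but 25% of the second adventitial list was at least 2-fold lower in both donors (29.4% of 17 genes without the filter), between the bounds set for and against, so this stays undecided with 12 genes. In donor A 9 of the 12 were at least 2-fold lower and in donor B 3, with medians of -1.44 and -0.727.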
